A study of Homo sapiens with 4 samples.

How the data were processed

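RNA immunoprecipitated with an EGFR antibody (EZ-Magna RIP kit) from MDA-MB-231 cells was labelled with Cy3 during reverse transcription and hybridised, 1 sample per array, to Agilent arrays of design 045997 by the authors. There were 2 EGFR WT and 2 EGFR KO arrays. Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1 under protocol GE1_1100_Jul11 at 3 microns, and the signals are intensity values, background-subtracted and spatially detrended, with surrogate values for dim spots and no scaling between arrays. The median spot and local background signals are also of unit intensity per the file headers, and the flags of unit other, 0 or 1 per spot, per the file headers. The mean spot signal planned for an alternative was absent, so the median signal was used there. The deposited series table holds log2 values that the authors quantile normalised, beside the floored intensity values, for 12,254 probes of non-coding transcripts in 17,432 rows, and 4 further columns of detection flags that were not used. Every row of it had at least 2 arrays flagged as present or marginal.

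Each array had 61,184 spots. The 1,439 control spots and 60 negative probes were left out, spots of a probe were averaged, and 24 probes with an outlier flag on an array were left out, which gave 58,941 probes of 60 bases. The signal was log2 transformed, and each array's 75th percentile was subtracted. The percentile was taken over the 18,891 probes well above background on all 4 arrays, as planned for the case that under 50% of probes were detected. Probes well above background on both arrays of at least 1 group were tested (25,028). The median signal over all probes was 8.67, 5.20, 8.75 and 11.4 on KO replicates 1 and 2 and WT replicates 1 and 2, against 2.24, 3.50, 3.08 and 3.13 over the negative probes.

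WT was compared with KO by limma 3.58.1 (lmFit and eBayes, two-sided, 4.04 prior and 2 residual degrees of freedom) in R 4.3.3 with data.table (version 1.17.8). Benjamini-Hochberg adjustment covered all tested probes, with a threshold of 0.05. The series states no pairing of replicates, and none was used. Slide numbers came from the file headers. Transcript names, relations to neighbouring genes and hg19 (GRCh37) coordinates came from the deposited table, whose starts count from 0 and were raised by 1. Gene symbols were updated with a RefSeq name table, of which no coordinate was used, and 2,642 of the listed probes carried a RefSeq symbol. A transcript that carries a coding gene's symbol is identified by its transcript accession. The probes outside the table have no annotation in the files, apart from 20 named by a RefSeq mRNA accession. No probe was named EGFR, so the planned EGFR value was not analysed. The table lists other matching transcripts for 2,227 probes, which an alternative left out.

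Of the named genes, 12 per direction were those with a gene symbol and the largest change among probes past the threshold, well above background on both arrays of the higher group and with non-overlapping groups. A further 2 per direction carried clone or locus names, and up to 4 members were named per gene list, those past the threshold first and otherwise those with the smallest unadjusted p. This rule, the limma comparison, the tests of the gene lists by symbol and the 26 gene lists were set before the data were examined. The mitochondrial list was an exception, since its members were matched by position on the mitochondrial chromosome and not by the symbols set beforehand. Additional names in the closing section, the list members PVT1, SNHG1, STRF6, cytochrome b and ND5, and the probes of reference mRNAs were chosen after the values were seen. The lists were tested by camera (preset correlation 0.01, lists of at least 5 genes, the brightest probe per gene) with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and by fry.

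Alternatives were normexp background correction (offset 50), quantile, median and all-probe percentile scaling, no scaling, no filter, detection on all 4 arrays, a replicate block, a slide block, an intensity trend with robust hyperparameters, the authors' table, leaving out each array, and other thresholds. With an array left out, its group has 1 array, which is assumed to vary like the other group. The slide block leaves the same contrast as leaving out KO replicate 1.

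On simulated data of 25,028 probes with the design of WT against KO, 200 changed probes were recovered in 6% of cases for a log2 change of 3 and 82% for 6, with 3 calls among unchanged probes. With 4,000 changed probes, 15.0% of changes of log2 1 to 2 and 89.3% of changes of 3 to 4 were recovered, and 4.45% of the calls were unchanged probes. With none changed, there were 0 calls. The simulations gave all 4 arrays of a probe the same spread and no slide effect. In the data the median absolute difference was 0.749 (log2) between the KO arrays and 0.318 between the WT arrays, so the rates may differ there. Of 40 simulated lists, the shifted one passed, and 1 of the others did. The search for sequence stretches recovered a planted rise of 1.5 (log2) as 0.917 or more in held-out probes, over 11,392 probes, and gave at most 0.146 with none planted. It used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.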

Results

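RNA recovered with an antibody against EGFR, the epidermal growth factor receptor, was measured in MDA-MB-231 cells, a triple-negative breast cancer line, on a 1-colour array for long non-coding RNA and mRNA. The 2 EGFR WT arrays came from untreated cells, and the 2 EGFR KO arrays from cells transfected with CRISPR/Cas9 knockout and homology-directed repair plasmids. The replicates were grown and harvested independently, 1 per array. Of 58,941 probes, 46.3% were well above background on KO replicate 1, 34.4% on KO replicate 2, 42.2% on WT replicate 1 and 46.1% on WT replicate 2. Across the 25,028 tested probes, Pearson's r was 0.963 between the WT arrays, 0.907 between the KO arrays and 0.781 to 0.817 between a WT and a KO array; probes are not independent replicates. The median absolute difference was 0.318 (log2) between the WT arrays, 0.749 between the KO arrays and 0.939 to 0.973 between a WT and a KO array. KO replicate 1 was alone on its slide, and the 3 other arrays shared the other slide. The number of arrays limits the precision.

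The comparison of WT with KO cells asked which RNAs were recovered with EGFR beyond what the same antibody recovered from cells in which EGFR had been targeted. Of the tested probes, 2,932 were higher in WT and 872 lower. Among named genes, 1 probe of TPT1-AS1, the antisense RNA of the translationally controlled tumour protein gene, was higher by 7.01 ± 0.533 (log2, SE, n = 2 arrays per group). A probe of HAGLR, a long non-coding RNA of the HOXD cluster, was higher by 6.28 ± 0.816. Of the tested probes, 1 of 13 passed for TPT1-AS1 and 3 of 7 for HAGLR, and both probes given here also match other transcripts. MIR155HG, the host transcript of the microRNA miR-155, was at least 9.39-fold higher in WT. An ALDH1L2 transcript without a coding annotation, NR_027752, was lower in WT by a log2 of -4.70 ± 0.984, and LNX1-AS2 by -3.64 ± 0.528. All differences are WT minus KO on the log2 scale. Where no array of the dimmer group was well above background, the difference is given as a fold of at least the stated size, with that group set at the mean of the lowest levels that were well above background on its arrays. Where 1 array of that group was not well above background, that array alone was set at its lowest such level, if it lay below it. Such bounds refer to the mean of the brighter group and not to each of its arrays.

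**Figure D1:**
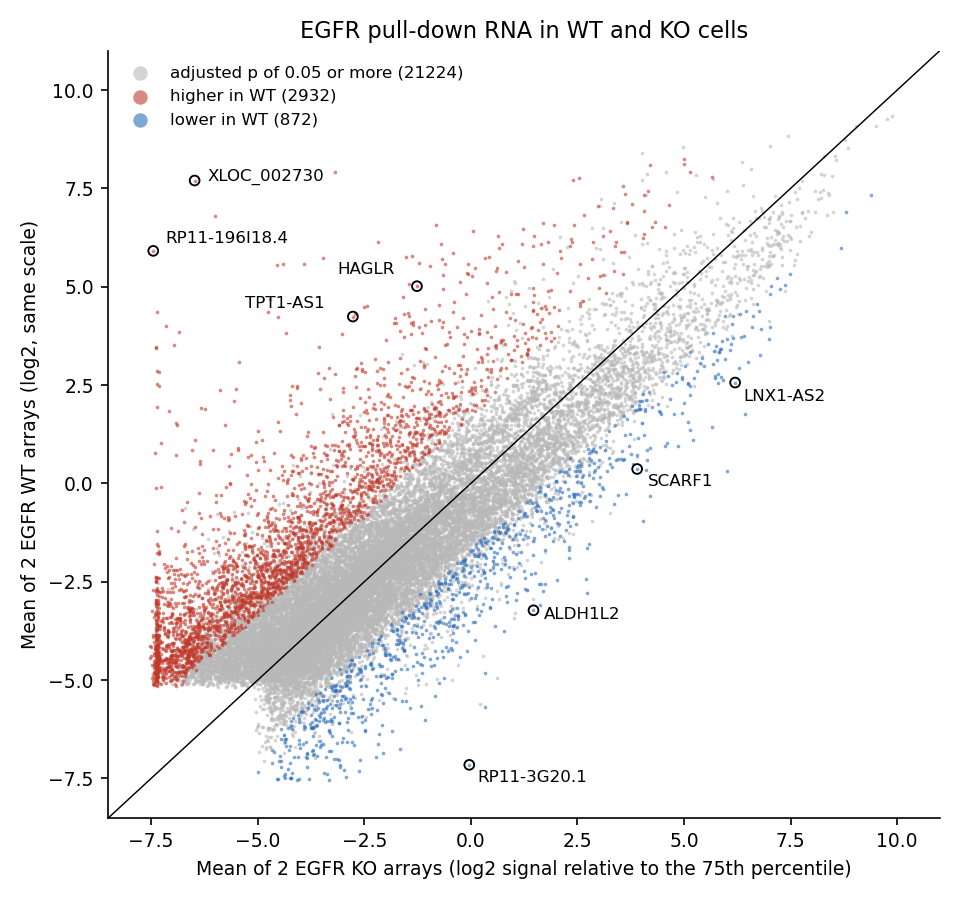
Mean log2 signal of the 2 WT arrays (vertical axis) against that of the 2 KO arrays (horizontal axis), relative to each array's 75th percentile, with 1 point per tested probe. Red points mark the 2932 probes higher in WT, blue points the 872 lower in WT, grey points the others, circles 8 named transcripts and the line equal signal.

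The transcript XLOC_002730 (TCONS_00006916), at hg19 chromosome 3, 96336045 to 96336983, was at least 8042-fold higher in WT, and RP11-196I18.4 (ENST00000427833), at chromosome 9, 109879740 to 109883986, at least 2328-fold. XLOC_002730 had 5 tested probes, of which 2 passed, both higher in WT, and 2 others had differences of -0.016 and -0.203. Among the named genes that were well above background in both groups, TPT1-AS1 (ENST00000517509; chromosome 13, 45915480 to 45965618; adjusted p = 0.00613 by limma) had a WT mean of 4.24 and a KO mean of -2.77. HCG25, in the major histocompatibility region and antisense to VPS52, was higher by 6.39 ± 0.622 (adjusted p = 0.00868 by limma). The pseudogenes HERC2P2 and RPS2P46 were higher by 6.25 ± 0.668 and 5.32 ± 0.423, and LINC01347 by 5.42 ± 0.941. HAGLR (ENST00000447538; chromosome 2, 177041108 to 177042812) had an adjusted p of 0.0114 by limma. The genes not well above background on a KO array were EGFEM1P (at least 38.0-fold), NAALADL2-AS3 (at least 36.5-fold), CCDC162P (at least 36.4-fold), SRGAP2B by its transcript NR_034178 (at least 23.0-fold), LGALS8-AS1 (at least 16.8-fold) and MIR155HG. LGALS8-AS1 had log2 levels of -2.75 and 0.34 on WT replicates 1 and 2, so its bound holds for their mean but not for WT replicate 1. Both WT arrays lay above both KO arrays for each of these 14 transcripts, as the rule for naming them required.

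In the other direction, RP11-3G20.1 (ENST00000518922; chromosome 8, 122684013 to 122696802) was at least 37.5-fold lower in WT, and LOC387647, antisense to SVIL, had a difference of -5.15 ± 0.873. RP11-3G20.1 had log2 levels of -2.81 and 2.74 on KO replicates 1 and 2, so its bound holds for their mean but not for KO replicate 1. LINGO1-AS1 and FRMPD4-AS1, well above background on 1 WT array each, were at least 9.75-fold and 7.92-fold lower, with adjusted p of 0.0359 and 0.0265 by limma. Without KO replicate 1 these became 0.0645 and 0.0541, and FRMPD4-AS1 had 0.0659 without WT replicate 1. LINC01617, also detected on 1 WT array, was at least 17.4-fold lower. LINC00222 had a difference of -4.01 ± 0.634 and the pseudogene OR7E14P of -3.72 ± 0.437. A MEG3 transcript, uc001yie.3, was at -4.33 ± 0.873. PLCL1 (ENST00000472193) and SCARF1 (NR_028076) were represented by transcripts that the authors listed as non-coding. That of PLCL1, detected on 1 WT array, was at least 11.8-fold lower in WT, and that of SCARF1 had a difference of -3.53 ± 0.643. LINC01094 and the pseudogene ANKRD26P1 were not well above background on either WT array and were at least 3.71-fold and 3.64-fold lower in WT. With normexp background correction, 9 of the 14 lower transcripts (all but LINC01617, LINC00222, OR7E14P, LNX1-AS2 and SCARF1) and, of the higher ones, CCDC162P and LGALS8-AS1 no longer passed, and RP11-3G20.1 also had an adjusted p of 0.0570 by limma with scaling by the median.

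**Figure D2:**
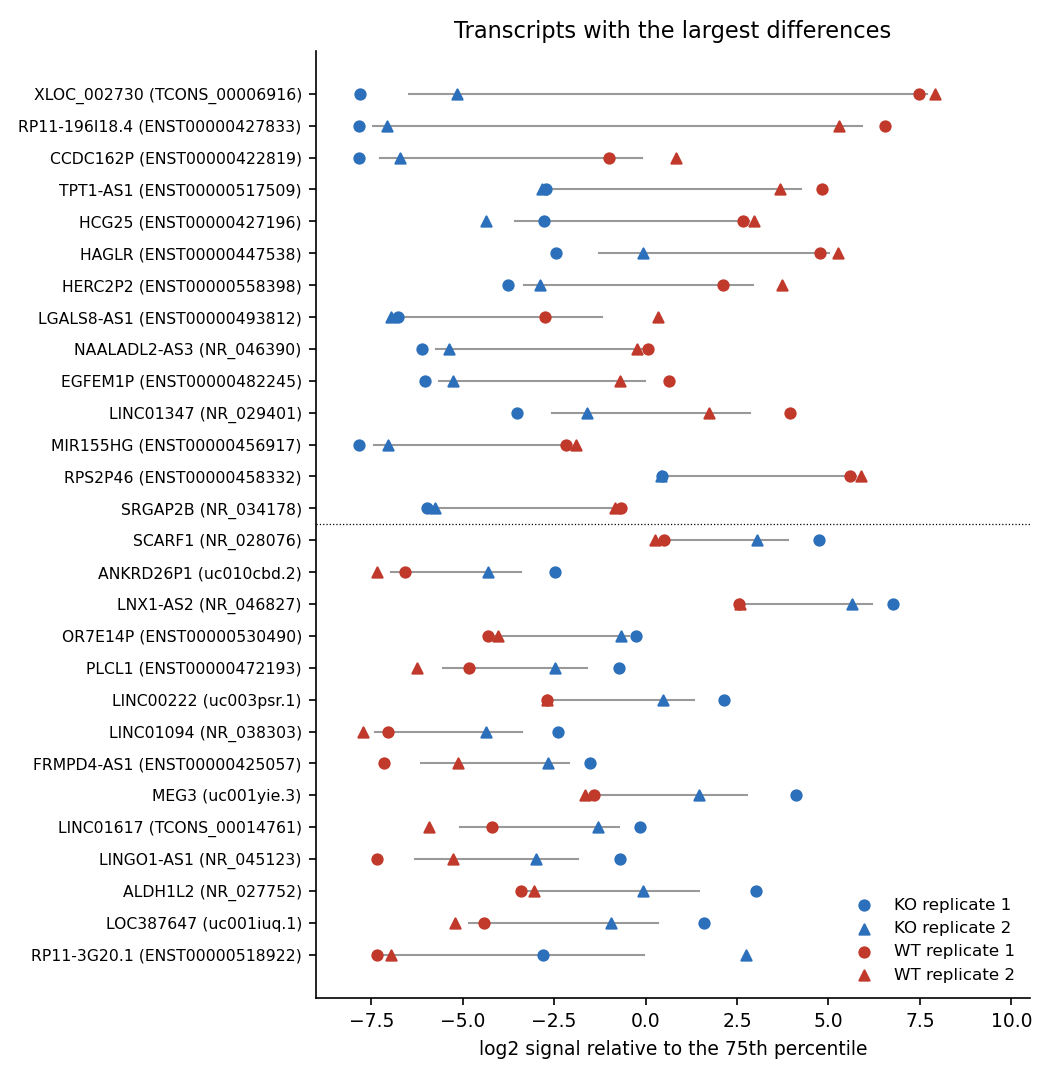
Log2 signal relative to the 75th percentile (horizontal axis) of the 28 transcripts with the largest differences (vertical axis), with 1 point per array: KO in blue, WT in red, replicate 1 as circles and replicate 2 as triangles, and grey lines joining the group means. Transcripts above the dotted line were higher on both WT arrays, from XLOC_002730 to SRGAP2B, and those below it were lower on both, as the naming rule required.

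Of the 25,028 probes, 3,804 had an adjusted p under 0.05 by limma, and 8,274 an unadjusted p under 0.05. Of the probes past the threshold, 77.1% were higher in WT, a share of 65.0% with scaling by the median of all probes (1,754 higher) and 88.4% without scaling (448 lower), and 85 rose 64-fold or more in the fitted difference against 2 that fell as far. With 2 arrays per group, an exact permutation test of a single probe cannot go below p = 0.333. Within the slide that held KO replicate 2 and both WT arrays, the count, equal to that without KO replicate 1 and to the fit with slide as a block, was 7,975 (5,156 higher and 2,819 lower). The count was 7,622 without KO replicate 2, 1,334 without WT replicate 1, 1,509 without WT replicate 2, 1,712 with another background correction (normexp), 5,314 with no filter on dim probes (1,608 lower) and 1,539 among probes well above background on all 4 arrays.

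Of the 11,392 tested probes that the authors list as non-coding, 1,812 passed (1,386 higher in WT and 426 lower). Intergenic transcripts gave 873 higher and 261 lower of 7,120. Natural antisense transcripts gave 169 higher and 36 lower of 1,251, intronic antisense transcripts 132 and 51 of 1,156, bidirectional ones 62 and 23 of 509, and exon sense-overlapping ones 63 and 19 of 545. Pseudogenes gave 14 higher and 13 lower of 227. The median difference was 0.10 for the listed non-coding probes and 0.12 for the 13,636 other probes, which no file annotates, so the comparison of non-coding with protein-coding RNA could not be made as planned. The difference of those medians was -0.016 (adjusted p = 0.949 by camera on the limma fit, for this single test), and it turned to 0.223 (adjusted p = 0.0244) with no filter on dim probes.

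Transcripts of the mitochondrial genome were higher in WT as a group. Their 9 probes had a median difference of 5.47 (adjusted p = 1.88e-04 by camera, on the limma fit), with an adjusted p = 0.272 with an estimated correlation and a median of 4.98 within the shared slide. Among all tested probes 5 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell. AF079515 (uc004coz.1), which spans the control region at positions 15999 to 16571, rose by 7.03 ± 0.465, and TVAS5 (uc004cos.4), at 1756 to 4264 across ribosomal RNA and ND1 sequence, by 6.50 ± 0.416. JA040725 and JA040723, on the minus strand, rose by 6.94 ± 0.690 and 6.51 ± 0.585, and STRF6 (uc004cov.4) by 5.47 ± 0.527. The transcript named for cytochrome b (uc022bqw.1), a subunit of respiratory complex III, fell by 2.05 ± 0.455 (adjusted p = 0.0358 by limma) and was the brightest of the 9, with a WT mean of 7.33 and a KO mean of 9.38. The 9 were matched by their position on the mitochondrial chromosome, since the files name them by clone. ND5, detected on 1 KO array, did not pass (adjusted p = 0.160 by limma).

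**Figure D3:**
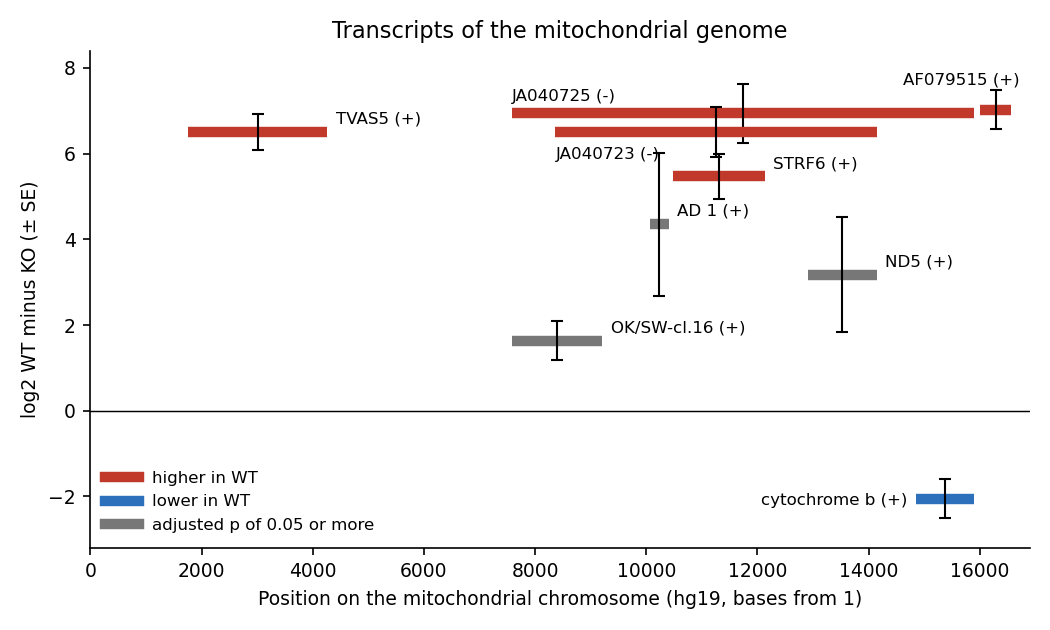
Difference between WT and KO (vertical axis, log2 WT minus KO, error bars SE, n = 2 arrays per group) of the 9 mitochondrial transcripts, drawn from start to end on the mitochondrial chromosome (horizontal axis, hg19, bases counted from 1) with the strand in parentheses. The 5 red bars lie between 5.47 and 7.03 and the blue bar, cytochrome b, at -2.05; the value of ND5 is the fitted one, with 1 KO array not well above background.

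Long non-coding RNAs linked to EGFR or breast cancer did not shift relative to other probes by camera, while fry, which tests whether a list's own genes move on balance one way, gave an adjusted p of 0.0205, upward in WT. Their 14 measured genes had a median of -0.165 and a mean of 0.303 (adjusted p = 0.943 by camera), and 4 of 42 probes rose and 1 fell, while adjusted over the list alone 2 genes rose. For comparison, 11.7% of all tested probes rose and 3.48% fell. In the brightest probes of these genes, CYTOR (ENST00000409898), a cytoplasmic long non-coding RNA, rose by 4.81 ± 0.464 and DANCR (NR_024031), which opposes cell differentiation, by 3.30 ± 0.424. Other probes of CYTOR, such as those at 1.29 and 1.14, and of DANCR, such as that at 0.67, did not pass. Single probes of HOTAIR (NR_047517), a partner of chromatin repressors, and of PVT1 (uc003ysj.2), next to MYC, rose by 2.25 ± 0.545 and 1.76 ± 0.447. A LINC00511 probe (ENST00000577773) fell by 2.38 ± 0.485. The brightest probes of these 3 genes did not pass, with -0.53 ± 0.531 for HOTAIR, 0.20 ± 1.19 for PVT1 and -1.19 ± 0.677 for LINC00511. Without WT replicate 1 the adjusted p was 0.299 for HOTAIR and 0.292 for LINC00511, and without WT replicate 2 it was 0.185 and 0.125. With normexp background correction these were 0.0602 for HOTAIR and 0.0501 for LINC00511. HOTAIR also missed the threshold with scaling by the median (0.0987) or the 75th percentile of all probes (0.0770) and among probes well above background on all 4 arrays (0.0580), and LINC00511 without scaling (0.0575).

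Nuclear long non-coding RNAs, 11 genes with a median of 0.61 (adjusted p = 0.787 by camera), had 5 of 53 probes higher and 2 lower, and none passed when adjusted over the list alone, with 1 probe per gene. Probes of MEG3, an imprinted long non-coding RNA, changed in both directions. Of its 24 probes 4 rose, with NR_046465 the highest at 4.25 ± 0.456, and 2 fell, with values of -4.33 for uc001yie.3 and -2.27 for NR_046469, the first of which has 12 other matching transcripts in the authors' table. For NR_046469 the adjusted p was 0.192 without WT replicate 1 and 0.277 without WT replicate 2, and for the MEG3 transcript ENST00000520069, higher in WT by a log2 of at least 2.32, it was 0.0937 and 0.121, and 0.0895 with normexp. JPX, from the X inactivation centre, was at least 1.94-fold higher in WT, but its call was not among those followed across the alternative settings.

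The host genes of small nucleolar RNAs, 13 genes with a median of -0.469 (adjusted p = 0.424 by camera), had 4 of 66 probes higher and 2 lower, and adjusted over the list alone 2 genes rose and 3 fell. SNHG29, whose other probes did not pass and lay on both sides of 0, fell in ENST00000580770, from a KO mean of 5.74 to a WT mean of 2.74, and was at least 2.84-fold lower in WT in ENST00000497774, with adjusted p of 0.112 and 0.206 without WT replicate 1 and, for the latter, 0.153 without WT replicate 2. The long non-coding RNA EPB41L4A-AS1 was at least 1.29-fold higher, and a SNHG1 probe (ENST00000537965) rose by 1.86 ± 0.415, while the brightest SNHG1 probe, at -1.04 ± 0.440, did not pass. EPB41L4A-AS1 and SNHG1 were not among the named transcripts whose calls were followed across the alternative settings. A single probe of GAS5, a gene induced on growth arrest (ENST00000455838), was at least 1.65-fold higher, with an adjusted p of 0.0594 without KO replicate 1 and 0.277 without WT replicate 1. With normexp background correction, GAS5 had 0.491 and SNHG29 ENST00000497774 0.153. GAS5 also had 0.0739 with scaling by the median and 0.0567 by the 75th percentile of all probes, and 0.0818 in the authors' table. Its other probes did not pass, with -0.60 ± 0.577 for the brightest (ENST00000449289) and -1.86 ± 0.524 for ENST00000422183 (adjusted p = 0.0648 by limma). Among small structural RNAs, RPPH1, the RNA of ribonuclease P, was at least 3.26-fold higher in WT, while SNORD3A (adjusted p = 0.132 by limma) and RMRP (-0.50 ± 0.439) did not pass. RPPH1 had an adjusted p of 0.222 with normexp.

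The files name few protein-coding genes, so most coding lists had no measured member. A non-coding transcript of SRSF6, a splicing factor of the RNA-binding list, was at least 11.5-fold higher in WT, and that of PSMG1, a proteasome assembly chaperone, at least 1.36-fold (adjusted p = 0.325 without WT replicate 1 and 0.207 without WT replicate 2). With normexp these had 0.0601 and 0.865, and PSMG1 had 0.0613 with scaling by the median and 0.0545 in the authors' table. SRSF2 (1.73 ± 0.457), HNRNPU (adjusted p = 0.542 by limma), the p53 targets TNFRSF10B (-1.73 ± 0.441), FAS (0.52 ± 0.470) and FDXR (0.17 ± 0.418), PFKL (-1.11 ± 0.431), LDHA (-0.08 ± 0.472), COX7A2 (-1.45 ± 0.580), NDUFA2 (-0.21 ± 0.416), IFITM3 (-0.43 ± 0.723), CXCL1 (-0.78 ± 0.511) and EDEM2 (-0.08 ± 0.530) did not pass. TNFRSF10B had an adjusted p of 0.0505, and of 0.0409 and 0.0301 without KO replicate 1 and KO replicate 2, 0.0399 with normexp, and 0.0451 and 0.0392 with scaling by the median and the 75th percentile of all probes. SRSF2 had 0.0553, and 0.0452 and 0.0489 without these arrays, 0.0480 with normexp and 0.0409 without scaling. Without KO replicate 2, PFKL had 0.0462, IFITM3 0.0382 and COX7A2 0.0261. The lists without a measured member were EGFR family and ligands, EGFR adaptors and degradation, ERK output genes, heat shock and chaperones, ribosomal proteins, replication-dependent histones, proliferation, extracellular matrix and integrins, mesenchymal and basal markers, luminal epithelial markers, leukocyte markers, fibroblast and endothelial markers, and cholesterol synthesis.

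A set of 20 RefSeq mRNA probes on the array gave the only values for identified coding transcripts. Of the 14 tested, MTX1, a mitochondrial import protein detected on 1 KO array, was at least 12.7-fold higher in WT (adjusted p = 0.0111 by limma), and the other 13 did not pass. KO replicate 1 had the lowest level of the 4 arrays for 16 of the 20. ACTB, beta-actin, had log2 levels of -6.98 and -1.48 on KO replicates 1 and 2, and -0.80 and -0.57 on WT replicates 1 and 2. RPLP1 and RPS18 of the ribosome were at -7.01 and -6.56 on KO replicate 1 and at -1.72 and -2.03 on KO replicate 2. GAPDH was not well above background on any array.

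Different probes of a gene did not share their difference. Over 1,222 genes with 2 probes that had no 10-base stretch in common, taken after the values were seen, the correlation of the difference across genes was 0.057 (95% bootstrap interval -0.018 to 0.147). It was 0.707 (0.576 to 0.816) over 279 genes with probes sharing 30 or more bases. Both probes passed in 30 of the 1,222 genes, 20 of them in the same direction, where independent probes with the pass rates of these pairs would give 27.9, and 1 probe alone passed in 310. TPT1-AS1 had 13 tested probes, of which 1 passed, and 1 passed of 4 for CCDC162P, 5 for EGFEM1P and 3 for HERC2P2. For HCG25 3 of 4 tested probes and for HAGLR 3 of 7 passed, all higher in WT. The values given for the named genes are those of 1 probe each. For 7 of the 28 transcripts with the largest differences, TPT1-AS1, HAGLR, LINC01347, RPS2P46, MEG3, LINC00222 and OR7E14P, the authors' table lists other transcripts that the probe matches, so their values are not specific to the transcript named.

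**Figure D4:**
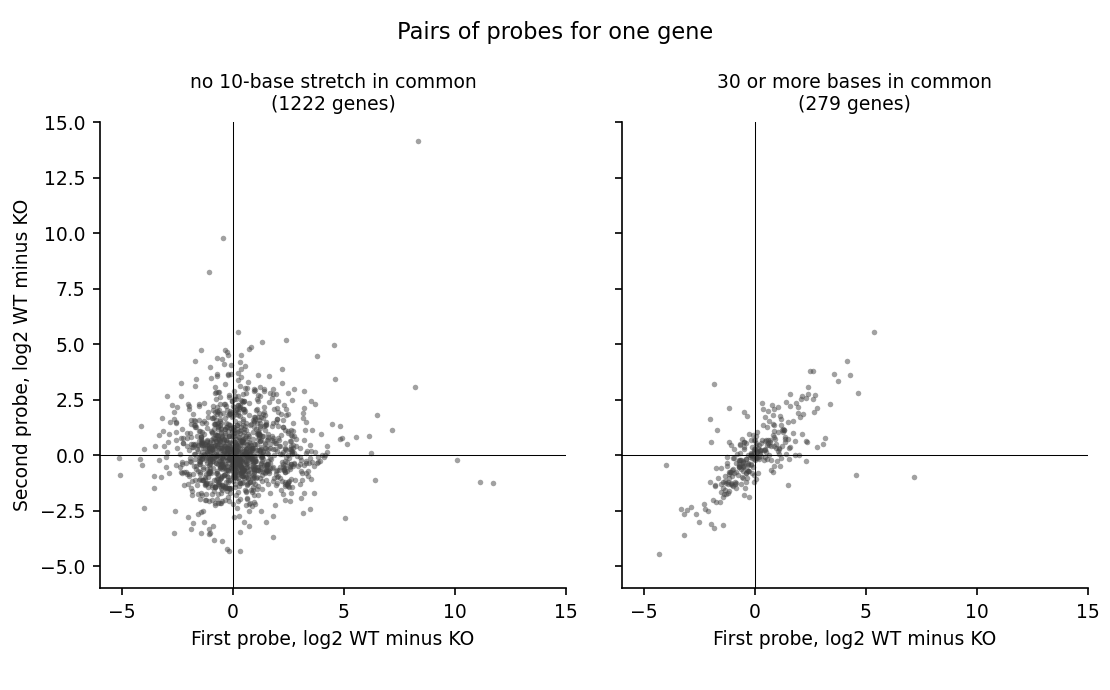
Difference between WT and KO (log2 WT minus KO, both axes) for a pair of probes of the same gene, with 1 point per gene. The left panel shows 1222 genes with probes that had no 10-base stretch in common (correlation 0.057) and the right panel 279 genes with probes sharing 30 or more bases (correlation 0.707).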

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

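Leaving out cross-hybridising probes and adjusting over the listed probes alone were chosen after the data were seen. The 3,804 probes past the threshold (2,932 higher in WT, 872 lower, 1,812 listed as non-coding) became 1,712 (1,191, 521 and 773) with normexp background correction, where the cause was not tested, and 1,539 (1,100, 439 and 703) among probes well above background on all 4 arrays, where fewer probes were tested. With slide as a block, which uses 3 arrays, they became 7,975 (5,156, 2,819 and 3,715). Leaving out 1 array gave 1,334 to 7,975 probes (1,100 to 5,156 higher, 234 to 2,966 lower, 665 to 3,715 listed); the lower counts came without a WT array, the higher ones without a KO array. An adjusted p under 0.1 gave 6,293 probes, and an unadjusted p under 0.05 with a 2-fold change 8,274. The higher probes fell to 1,754 with scaling by the median of all probes. The lower ones numbered 448 without scaling and 1,608 with no filter on dim probes, and the cause was not tested. Replicate numbers did not pair the arrays (r = -0.058), and a replicate block gave 4,415 probes. Relative to the median of all tested probes at 0.112, scalings shifted that median by -0.282 (median) to 0.289 (none), and the share of higher calls ran from 65.0% (median) to 88.4% (none). It was 64.7% without KO replicate 1 and 61.1% without KO replicate 2. Leaving out the cross-hybridising probes gave 3,502. Among the probes past the threshold in the main fit, 3 had a fitted difference of opposite sign with normexp, whether or not they passed there. None did in the other refitted settings that measured them. The authors' table, which covers the listed probes, gave 1,636 of them and no value for the other counts.

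Of the 4 lists tested, 1 passed by camera, 0 with an estimated correlation and 2 by fry, a test of another question (mitochondrial genome and long non-coding RNAs linked to EGFR or breast cancer). The median of listed minus unlisted probes, -0.016, became 0.223 with no filter on dim probes, a setting that adds dim probes mostly to the unlisted side, since the table holds only probes detected on 2 or more arrays. For 59 named transcripts, 907 values under 16 settings held 843 unchanged calls, 50 lost and 14 gained, with 0 reversals, and 19 of the losses came with normexp. Signal over background limits the folds of transcripts with an undetected array in the dimmer group, and those named as changed are given as lower bounds.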

Other observations

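Among the tests below, the correlation between probes of a gene, the search for shared stretches, the test on housekeeping genes and both tests on KO replicate 1 were chosen after the results were seen, as was the use of neighbouring genes in place of list members.

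Non-coding transcripts that the authors pair with a protein-coding neighbour were used in place of the members of the coding lists. Their values are those of the non-coding transcripts and not of the neighbour's mRNA. Of the paired probes, 5 of 16 for extracellular matrix and integrins and 2 of 8 for EGFR adaptors and degradation passed as higher in WT, and 0 as lower. RP11-179H18.8, antisense to the HSP70 co-chaperone gene BAG3, was at least 113-fold higher in WT. For matrix genes, RP11-177H13.2, antisense to LOXL2 and detected on 1 KO array, was at least 58.7-fold higher, and RP11-725K16.4, antisense to the collagenase gene MMP1, rose by 5.32 ± 0.481 (log2, SE, n = 2 arrays per group). For genes of EGFR degradation, LA16c-313D11.10, beside the ubiquitin ligase gene STUB1, rose by 4.86 ± 0.458, and RP11-191G24.1, in an intron of the endocytic adaptor gene EPS15, was at least 3.76-fold higher. TGFA-IT1, in the gene of an EGFR ligand, rose by 2.32 ± 0.484. RP11-399O19.5, paired with ACTA2, was at least 7.84-fold higher, and LOC729421, paired with G3BP1, fell by 1.84 ± 0.438.

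By these neighbours, the medians were 1.70 for EGFR adaptors and degradation (7 genes), 1.46 for the proteasome (9), 0.96 for ribosomal proteins (6), 0.68 for proliferation (6), 0.64 for the interferon response (8), 0.50 for heat shock and chaperones (5), 0.37 for p53 targets (10), 0.24 for extracellular matrix and integrins (14), 0.11 for RNA-binding proteins (7), -0.08 for the unfolded protein response (7), -0.28 for cholesterol synthesis (7), -0.37 for glycolysis and hypoxia (7), -0.38 for luminal epithelial markers (5) and -0.47 for mesenchymal and basal markers (5). None passed camera, with a smallest adjusted p of 0.412 and, with an estimated correlation, 0.871. By fry, heat shock and chaperones had an adjusted p of 0.0229, ribosomal proteins 0.0249 and extracellular matrix and integrins 0.0303. In these lists 1 of 5, 2 of 6 and 4 of 14 genes passed the threshold, all higher in WT. Their mean differences of 1.78, 1.13 and 0.87 lay above their medians, and whether single genes carried the fry results was not tested. The lists too small to test had medians of 1.12 for fibroblast and endothelial markers, 0.65 for EGFR family and ligands, 0.33 for leukocyte markers, 0.18 for oxidative phosphorylation, -0.06 for ERK output genes, -0.44 for replication-dependent histones and -0.78 for NF-kB and cytokines.

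Probes of a gene did not move together, with a correlation of 0.0571 over 1,222 genes and an interval of up to 0.147. The differences themselves were repeatable, since WT minus KO of replicates 1 and of replicates 2 correlated at 0.673 across the listed probes. Log2 levels of the paired probes also correlated at only 0.001 to 0.056 within an array. Probes that do not share a gene's level could not show a change shared by all its transcripts, so these pairs cannot decide whether there was one. Short sequence stretches shared by unrelated probes are a candidate explanation. Held-out carriers of 8-base stretches chosen in other probes for WT lay above the non-carriers by a median of 0.908 over 20 splits (0.654 to 1.17). Those chosen for KO lay below, at -1.23 (-1.32 to -1.02). Chosen in the same way for the difference of the WT arrays, stretches gave medians of 0.254 and -0.058. For KO replicate 1 minus 2 they gave 0.586 and -1.19 (-1.27 to -0.966). A downward effect of similar size thus also lay between the KO replicates, so it is not particular to WT against KO. Carriers with the stretch near the free 5' end of the probe did not differ more than those with it near the surface (0.028, interval -0.121 to 0.180), which argues against an effect stronger at the free end, while a sequence preference in the recovered RNA, other hybridisation and differences between isoforms stay open as untested.

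Natural antisense transcripts made up 23 of the 60 listed probes that rose 64-fold or more (38.3%) and 10.8% of the others (odds ratio 5.12, two-sided Fisher's exact p = 2.98e-08, over probes, which are not independent). Neither this comparison nor its 64-fold cut was part of the plan. At 4-fold or more, 150 of 1,225 listed probes that rose were natural antisense, as were 1,251 of the 11,392 tested listed probes. Of all tested natural antisense probes, 13.5% passed the threshold as higher in WT at any size, against 12.2% of all tested listed probes. Repeats of one sequence are argued against, since the 23 probes formed 22 families by a shared 16-base stretch (95.7%). Labelled copies of abundant sense mRNAs, read by antisense probes, could not be excluded: the 13 natural antisense probes paired with genes of 6 housekeeping lists lay above the others by 0.442, with a 95% bootstrap interval from -0.886 to 2.05 that is too wide to decide. Recovery of antisense RNA with EGFR stays open and was not tested.

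KO replicate 1 was on a slide of its own. Of 2,235 probes that differed 8-fold or more between it and WT replicate 1, 96.2% kept their direction between KO replicate 2 and WT replicate 2 on the shared slide, with a median size of 2.57 against 3.81 (log2). This argues against the slide as the whole source of the differences. Less RNA on that array stays open: 46.3% of its probes were well above background, against 46.1% on WT replicate 2, but its negative probes were the dimmest (2.24) and it had the lowest level for 16 of the 20 reference mRNAs. Clonal or culture differences between the WT and KO cells coincide with the groups, and total RNA without a pull-down was not measured, so recovery with EGFR and abundance in the cell stay open and untested.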
